A study of Homo sapiens with 2 samples.

How the data were processed

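Total RNA from 2 samples of NCI-H460 cells, 1 with the empty vector and 1 with stable expression of an siRNA against DUSP1, was hybridised to 1-colour Affymetrix expression arrays, 1 array per sample. Per the labels' protocols, RNA was extracted with TRIzol and purified on a column, cDNA was made with the One-Cycle kit, and cRNA was labelled with biotin by in vitro transcription. The same labels say that clones expressing the siRNA were selected with puromycin, and whether 1 clone or a pool of clones was hybridised is not given in the sources used here. Affymetrix scanner files were not used here.

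The values deposited by the authors are probe set intensities on a linear scale. The submitters' processing notes name RMA (background correction, quantile normalization between arrays and summary of probes into probe sets), with no version. RMA gives log2 values, so the deposited intensity values, which run from 5.92 to 22131, appear to have been turned back to a linear scale. This reading rests on the values. The sorted log2 values of the arrays differ by at most 0.08, which fits values already normalized between arrays, so no further normalization was applied. RMA compresses differences at low levels, so folds of dim genes are understated. No detection call was used here. No genome build is named in the sources used here and no coordinates are printed.

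From there, log2 of each intensity was taken without a pseudocount. Probe sets were named from the platform annotation, in which 41097 had 1 gene symbol and 1801 several, and 11721 others were unnamed here. The 62 control probe sets were kept apart. Of the probe sets with 1 symbol, 41043 were updated to a current symbol through their Entrez ID with a gene table of assembly GRCh38.p14, and 54 kept the older symbol. Probe sets with several symbols were not used for genes. Each of 19775 genes took the values of its brightest probe set, by the mean of both arrays. Different probe sets of a gene can disagree, and the report gives how many agree where it matters. A gene counted as at or above the median level when its mean log2 was at least 4.68, the median over all probe sets, which left 12861 genes.

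With 1 array per group there is no residual degree of freedom, so no p-value, standard error or adjusted p was computed. Genes at least 2-fold apart (1 on the log2 scale) were counted as a fixed rule of size. For each of 36 gene lists the median difference was compared with 10000 random lists of the same size, drawn from the same 20 bins of mean level, with a fixed seed. Members entered whatever their level, and DUSP1 was left out of its own list. Members without a probe set named for that gene alone were not analysed here. The named genes were DUSP1, the 15 genes higher and the 15 lower by the most among genes at or above the median level, and the 4 members of each list with the largest absolute difference. The lists, the rules and the alternatives, apart from those said to be chosen later, were fixed before the data were examined. The lists were MAP kinase phosphatases, immediate-early genes, ERK output, MAP kinase cascade, angiogenic factors, angiogenesis inhibitors, matrix proteases, extracellular matrix, integrins and adhesion, epithelial, mesenchymal, growth factor receptors and ligands, inflammatory, interferon-stimulated, antigen presentation, p53 targets, mitotic, DNA replication, hypoxia and glycolysis, NRF2, ATF4 and unfolded protein response, heat shock, cholesterol synthesis, TGF-beta targets, Wnt and Notch targets, apoptosis, small RNA machinery, cancer-testis, lung lineage, neuroendocrine, fibroblast, endothelial, leukocyte, ribosomal protein and oxidative phosphorylation genes.

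Control probe sets gave the spread of differences at probe sets meant to be equal: 18 for hybridization spike-ins, 24 for poly-A spike-ins and the 100 numbered 200000 to 200099, which the manufacturer placed on the arrays for normalization. Those 100 include probe sets of human genes such as RPL11 and RPL6, so their spread also holds any difference between the RNA samples. Alternatives covered the probe set rule, the scaling of the arrays, the filter on level, the 2-fold rule and the matching of random lists, and shifts of all differences to the median of each set of control probe sets were added after seeing the data. Runs of neighbouring genes were sought with the median of 50 consecutive genes in the order of the same assembly, against 100 shuffles within level bins, and sex chromosomes were left out. After the runs were seen, they were sought again on alternate genes, and the genes between that were not used were examined. The scripts were tested on simulated data made from the real levels with a noise SD of 0.2: all 50 genes at each change of 1.5 and of 2 in either direction were called among 12861 genes, 0 of 12661 unchanged genes were, and 36 of 36 lists shifted by 0.3 lay above the random range. With noise this small against the 2-fold rule, these outcomes were nearly fixed in advance. They check the scripts and give no rate of false calls on the real arrays. The real differences had a robust SD (from the median absolute deviation) of 0.26 over genes at or above the median level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.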

Results

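Gene expression was measured in NCI-H460, an established human non-small cell lung cancer cell line, on Affymetrix expression arrays. One of the samples carried the empty pSuperRetro vector and the other stably expressed an siRNA against DUSP1, a dual-specificity phosphatase (also called MKP1) that switches off MAP kinases. Each condition was measured on 1 array, so no value below has a replicate error, no difference was tested, and every statement compares these 2 RNA samples. The number of arrays limits the precision. Each array gave 54675 probe set intensities, with a median of 25.8 for the empty vector and 25.6 for the DUSP1 siRNA. Differences are given as the log2 intensity with DUSP1 siRNA minus that with empty vector, and 1 on this scale is 2-fold.

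DUSP1 itself was lower in the cells that expressed the siRNA. Its brightest probe set (201041_s_at) read 4299 with empty vector and 1277 with DUSP1 siRNA, a difference of -1.75 or 3.37-fold. The next brightest (201044_x_at) read 475 and 144, or 3.31-fold lower. The dimmest (226578_s_at) read 72.1 and 64.8, a 1.11-fold difference. The target gene was thus lower at its brightest and next brightest probe sets, which is the direction the labels give, while the dimmest hardly differed.

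By the brightest probe set of genes at or above the median level, LUM and SERPINB11 were lower by the most with DUSP1 siRNA. LOXL2 and GJA5 were higher by the most. This order depends on which probe sets are taken. Of 12861 genes at or above the median level, 85 were at least 2-fold higher and 232 were at least 2-fold lower with DUSP1 siRNA, so 73.2% of the 317 genes that differed this much were lower. The other 12544 genes differed by less than 2-fold. This split depends on the scaling of the arrays: with all differences shifted by 0.21 to put the median poly-A spike-in RNA at 0, 142 were higher and 149 lower, and with a shift of -0.41 to put the median hybridization spike-in RNA at 0, 47 were higher and 735 lower. All differences given here are therefore relative to the bulk of genes. For scale, the 100 normalization control probe sets differed by 0.04 at the median with an SD of 0.13 across probe sets, and none reached 2-fold. Those were placed on the arrays for normalization, so their spread may understate that of other genes. The robust SD of the differences over all genes at or above the median level was 0.26. The 2-fold rule is a rule of size and not a test.

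Among genes at or above the median level, those lower by the most with DUSP1 siRNA were LUM, which encodes the collagen-binding proteoglycan lumican (8.74 to 3.62 on the log2 scale, a difference of -5.12), and the serpin gene SERPINB11 (10.12 to 5.02, -5.09). LUM rests on 1 probe set, since its other probe set lay below the median level and differed by -0.25. NAV2, a neuron navigator gene, was lower by all 3 of its probe sets at or above the median level (-3.98 at the brightest), but the probe set that is taken when those with an _s or _x suffix are passed over differed by 0.11. PLA2G7, the enzyme that hydrolyses platelet-activating factor, differed by -3.68, and HPGDS, a prostaglandin D synthase, by -2.67. PXDN, which encodes peroxidasin, an enzyme that cross-links collagen IV, differed by -3.29 and was lower at both of its probe sets. SH2D2A, an SH2-domain adaptor, went from 11.82 to 8.35, and the forkhead transcription factor gene FOXQ1 went from 11.40 to 8.29. The other genes among the 15 lower by the most were PIP5K1B (-3.55, but -0.24 at its other probe set), PTCHD1 (-3.26), CYTIP (-3.15), LRATD2 (-3.07), IL13RA2 (-2.93), the non-coding RNA LINC03125 (-2.78) and FGF14 (-2.75).

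Those higher by the most were LOXL2, a lysyl oxidase that cross-links collagen (4.52 to 8.68, a difference of 4.17), and GJA5, which encodes the gap junction protein connexin 40 (4.31 to 8.48, 4.16). NNMT, nicotinamide N-methyltransferase, differed by 3.90, and the fibril-associated collagen gene COL12A1 by 3.34. COL3A1, which encodes the chain of type III collagen, differed by 2.86 and was at least 2-fold higher at 3 of its 5 probe sets, while the others differed by 0.04 and 0.13. At least 2-fold differences were read at 2 of 4 probe sets of LOXL2 and 2 of 5 of COL12A1. Genes of cell surface receptors were also among the 15 higher by the most. SUCNR1, the succinate receptor, differed by 3.26, S1PR3, a sphingosine 1-phosphate receptor, by 3.15, ROBO1, a receptor of SLIT ligands, by 2.33 and C5AR1, the complement C5a receptor, by 2.16. The secreted factors WNT5A (2.24) and GDF15 (2.09) were also higher. The remaining genes of this group were VIT (2.67), NDST4 (2.58), S100A3 (2.57) and CPLX2 (2.49). Of the 30 genes that differed by the most in either direction, 12 read below the median level of all probe sets (4.68) on the dimmer array, where the size of a difference is uncertain. As the mean of all their probe sets 11 of the 30 differed by over 1.5 times less. Among them were LOXL2 (1.40), COL12A1 (1.12), S1PR3 (1.69), NDST4 (1.24), CPLX2 (1.37), LUM (-2.68), NAV2 (-1.22) and LRATD2 (-1.14). Genes with 1 probe set could not change under this rule and have no second reading. SERPINB11, PLA2G7, SH2D2A, FOXQ1 and SUCNR1 are among these.

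**Figure D1:**
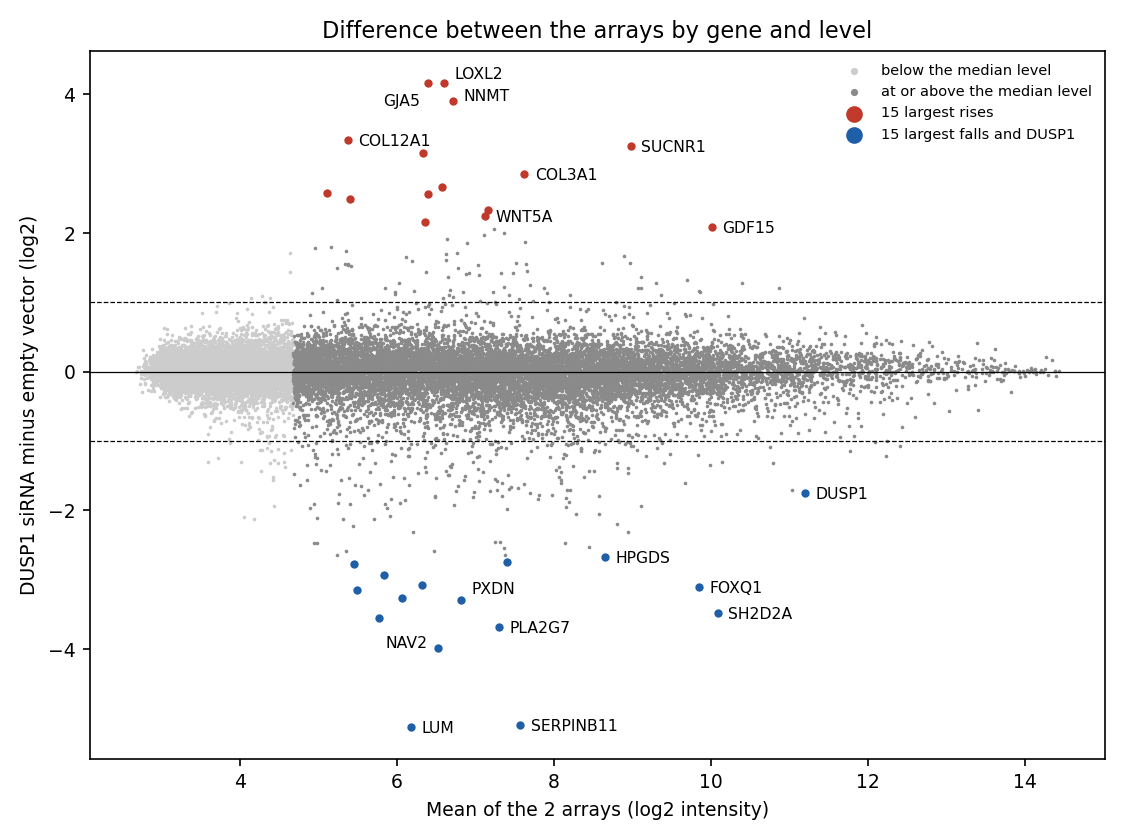
Difference between the DUSP1 siRNA and empty vector arrays (y axis, log2) against the mean log2 intensity of the 2 arrays (x axis), with 1 point per gene. Dashed lines mark 2-fold; the lowest point is LUM at -5.12, the highest is LOXL2 at 4.17, and DUSP1 lies at -1.75 among the brighter genes.

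To describe pathways, 36 gene lists were fixed before the data were examined, and the median difference of each was placed among 10000 random lists of the same size and level. The medians of 8 lists lay above the central 95% of the random medians, called the random range below, and those of 5 lay below it. If genes varied independently, 1.8 of the 36 would lie outside by chance. Members of a list can vary together and some lists share members, so these counts cannot be weighed against 1.8 as a test. These percentiles describe the 2 arrays, in which genes are not replicates. Of the 71 genes at least 2-fold apart that the text names by rule besides DUSP1, 10 were under 2-fold as the mean of all their probe sets: ATF3 (0.94), JAG1 (0.89), COL4A1 (0.69), MCAM (-0.79), ITGA6 (-0.98), KRT19 (-0.82), AXL (0.87), TWIST2 (-0.73), MERTK (-0.84) and IL1A (0.66). Named genes with 1 probe set, such as CCN2, could not change under this rule.

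**Figure D2:**
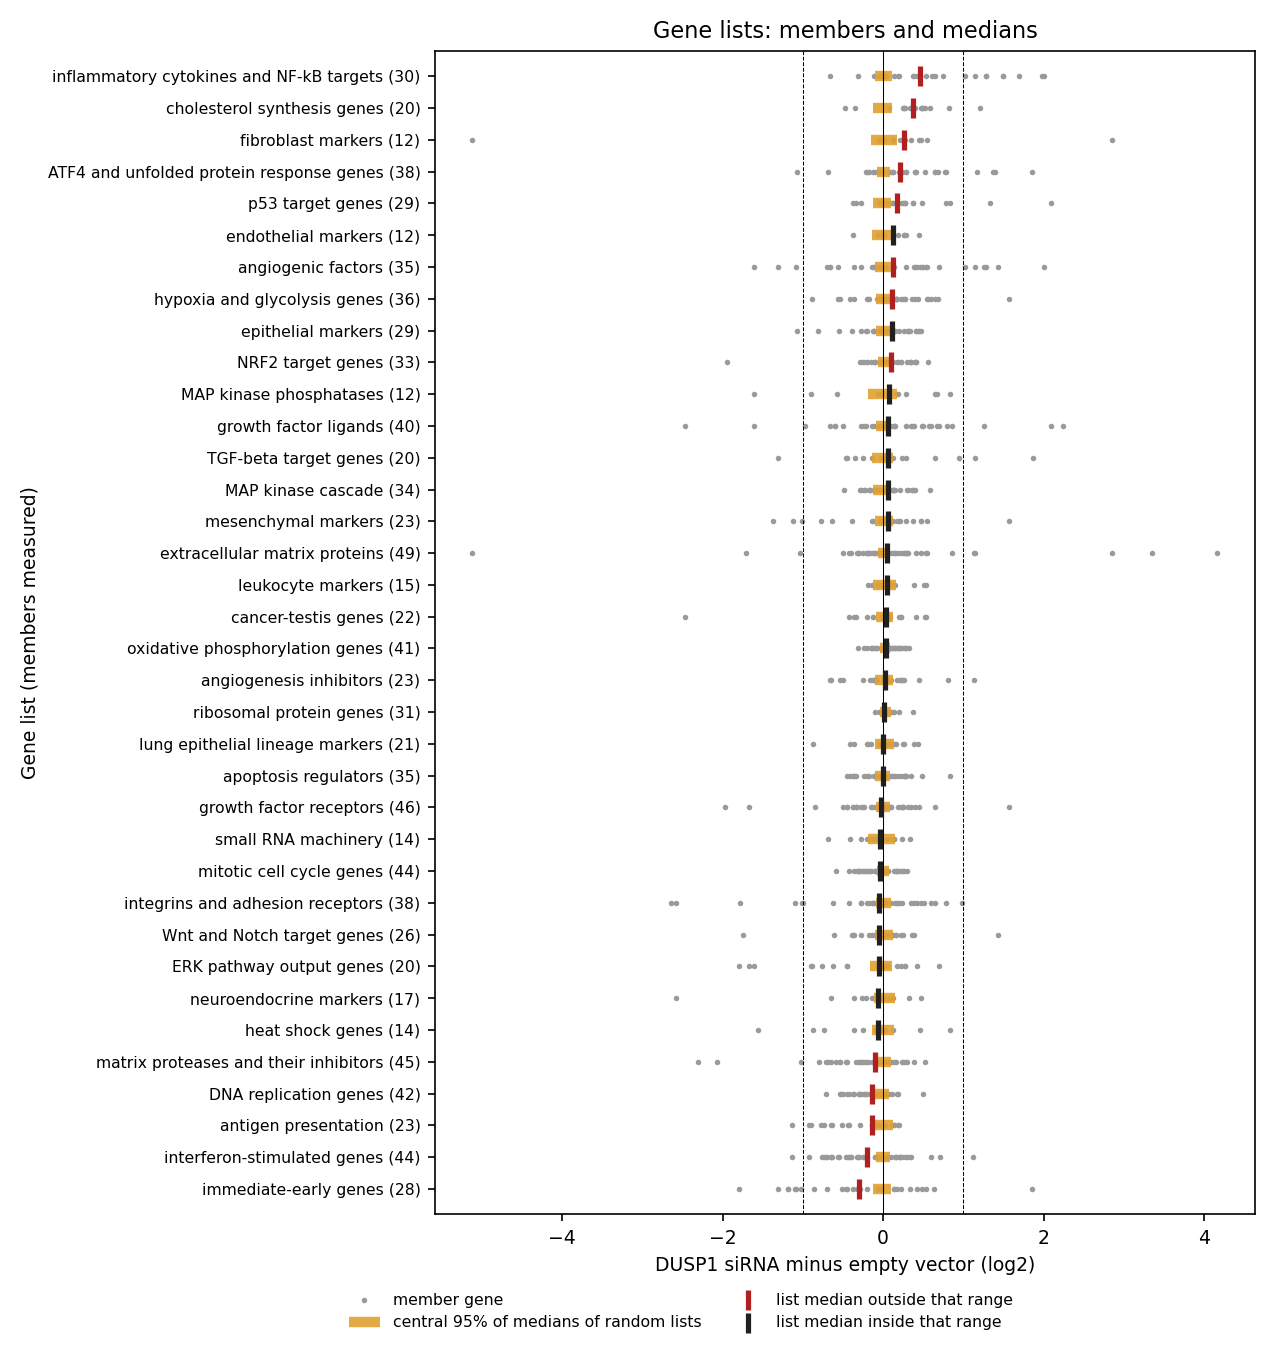
Differences between DUSP1 siRNA and empty vector (x axis, log2) for the members of 36 gene lists (y axis, number of members measured in brackets). Grey points are genes, the vertical bar is the list median, orange spans the central 95% of medians of 10000 random lists, and dashed lines mark 2-fold; inflammatory genes have the highest median (0.46) and immediate-early genes the lowest (-0.31).

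The title of the study names angiogenesis, invasion and metastasis. Among angiogenic factors, VEGFC, the lymphangiogenic growth factor, was 3.06-fold lower with DUSP1 siRNA (8.42 to 6.81), and CCN2, which encodes connective tissue growth factor, was 2.49-fold lower. The chemokine CXCL3 was 4.01-fold higher. The Notch ligand JAG1 was 2.69-fold higher at its brightest probe set, and higher by any amount at 3 of its 4 probe sets at or above the median level. Of 35 angiogenic factors measured, 6 were at least 2-fold higher and 3 at least 2-fold lower, and the list median of 0.12 lay at percentile 99.45. That position came with 7 members shared with the inflammatory list: the other 28 had a median of -0.00, with 14 higher and 14 lower, at percentile 48.2. The angiogenic list also lay inside the random range under 2 of 8 alternative settings. Among these 8, the setting that shifts all genes alike could not change any list's position. Of 23 angiogenesis inhibitors, COL4A1 alone was at least 2-fold higher (1.13), none was at least 2-fold lower, and the list median was 0.02 at percentile 56.8. SEMA3A differed by 0.81, SEMA3F by -0.67 and ADAMTS1 by -0.65.

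Single genes of matrix breakdown read lower with DUSP1 siRNA, while the members of their list went both ways. PLAT, tissue plasminogen activator, was 4.94-fold lower (7.35 to 5.05), the stromelysin gene MMP10 was 4.21-fold lower (6.95 to 4.87), and PLAUR, the urokinase receptor, was 2.04-fold lower at its brightest probe set and lower at all 3. ADAM19 differed by -0.80. Of 45 matrix proteases and their inhibitors, 29 were lower and 16 higher, 3 were at least 2-fold lower and none at least 2-fold higher, and the list median of -0.10 lay at percentile 0.71. The list holds proteases and inhibitors of proteases alike. Among inhibitors, TIMP2 (-0.54) and TIMP4 (-0.69) were lower and TIMP3 (0.24) was higher. The proteases MMP19 (0.39) and ADAM17 (0.52) were among the higher members.

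Matrix proteins differed in both directions and adhesion receptors mainly read lower among those 2-fold apart. Of 49 extracellular matrix genes, 5 were at least 2-fold higher, among them LOXL2, COL12A1 and COL3A1, and 3 at least 2-fold lower, among them LUM, and the list median was 0.05 at percentile 83.1. COL3A1 lies within a run of neighbouring genes, most of which were slightly lower. Of 38 integrins and adhesion receptors, none was at least 2-fold higher and 5 were at least 2-fold lower. These included the heparan sulfate proteoglycan SDC2 (-2.64), the neural cell adhesion molecule NCAM1 (-2.59) and the laminin receptor subunit ITGA6 (-1.10). MCAM differed by -1.79 at its brightest probe set but was lower at only 1 of its 2 probe sets at or above the median level, and the list median of -0.05 lay at percentile 11.6, inside the random range.

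DUSP1 acts on MAP kinases, so their phosphatases, target genes and cascade were examined. The immediate-early genes, which MAP kinases induce, were lower as a group with DUSP1 siRNA. The transcription factor gene EGR1 was 3.47-fold lower, and the orphan nuclear receptor NR4A2 was 2.28-fold lower. ATF3, in contrast, was 3.62-fold higher. Of 28 immediate-early genes, 18 were lower and 10 higher, 7 were at least 2-fold lower and 1, ATF3, at least 2-fold higher, and the median of -0.31 was below those of all 10000 random lists. Among the 12 other MAP kinase phosphatases, DUSP6, which acts on ERK, was 3.04-fold lower at its brightest probe set and lower at all 3. DUSP4 differed by -0.90, DUSP10 by 0.83 and DUSP9 by 0.67, and this list had a median of 0.08 at percentile 82 and a mean of -0.03. Of 20 output genes of the ERK pathway, EGR1, DUSP6 and the ephrin receptor EPHA4 (-1.67) were at least 2-fold lower and none was at least 2-fold higher. The median of that list, -0.06, lay at percentile 27.0 while its mean was -0.36. None of the 34 measured genes of the MAP kinase cascade differed by 2-fold, and their median of 0.06 lay at percentile 89.4. Within the cascade, MAP3K5 (0.58), MKNK1 (-0.48), MAP2K2 (0.40) and MAPKAPK3 (0.38) differed most.

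Of the 36 lists, inflammatory genes had the median farthest from 0. CCL20, a chemokine that attracts lymphocytes and dendritic cells, was 3.93-fold higher with DUSP1 siRNA, the nuclear NF-kB regulator NFKBIZ 3.24-fold higher, and the cytokine gene IL1A was higher at a low level (4.49 to 5.99). The IL1A reading rests on this probe set, since its other probe set differed by -0.17. Of 30 inflammatory cytokines and NF-kB targets, 24 were higher and 6 lower, 9 were at least 2-fold higher and none at least 2-fold lower, and the list median of 0.46 was above those of all 10000 random lists. The bright genes IL6 (-0.67) and TNFAIP3 (-0.31) were among the 6 lower. All 5 CXC chemokines on the list, a subgroup chosen after the values were seen, were higher, from 0.46 for CXCL8 to 2.00 for CXCL3.

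Interferon-stimulated and antigen presentation genes were lower by smaller amounts. PSMB9, an immunoproteasome subunit, was 2.20-fold lower with DUSP1 siRNA. The HLA class I genes HLA-B, HLA-F and HLA-C were lower by 1.90-fold, 1.87-fold and 1.71-fold, and each was lower at every one of its probe sets at or above the median level. These near-identical genes can share labelled RNA on the arrays, so their separate values are uncertain. Of 23 antigen presentation genes, 17 were lower and 6 higher, with 1 at least 2-fold lower, and the median of -0.14 lay at percentile 0.65. Of 44 interferon-stimulated genes, 27 were lower and 17 higher, and the median of -0.21 was below those of all 10000 random lists. IFI44L went the other way and was 2.16-fold higher, and MX2 differed by -0.76 at a low level. The lists share 4 members, and the interferon list without them had a median of -0.10. Neither list was placed among random lists without the shared members, so how far each position rests on them stays open.

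The lists of ATF4 and unfolded protein response genes, p53 targets and cholesterol synthesis genes had medians above the random range. ATF3, the glutathione-degrading enzyme gene CHAC1 (1.39), the transcription factor gene DDIT3, also called CHOP (1.37), and NUPR1 (1.18, inside a run of neighbouring genes that were mostly slightly lower) were the 4 genes of the ATF4 and unfolded protein response list that were at least 2-fold higher. Of its 38 members 26 were higher and 12 lower, with 1 at least 2-fold lower, and the median of 0.21 was above those of all 10000 random lists. Among 29 p53 target genes 24 were higher, led by the secreted factor gene GDF15 (2.09) and the growth arrest gene GADD45A (1.33). The p53 list median of 0.17 lay at percentile 99.9, and PMAIP1 (0.83) and SESN2 (0.78) were higher by less than 2-fold. SESN2 is also on the ATF4 list, so the lists are not independent. MDM2 (0.48) and CDKN1A (0.27) were higher by less, and 5 members were lower, FAS (-0.37) and PLK2 (-0.34) among them. Of 20 cholesterol synthesis genes 18 were higher. HMGCS1, the HMG-CoA synthase of that pathway, was 2.32-fold higher, LSS, lanosterol synthase, 1.77-fold and NSDHL 1.43-fold, while SQLE, squalene epoxidase, differed by 0.58. The cholesterol list median of 0.37 was above those of all 10000 random lists.

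List medians were nearer to 0 for the other metabolic and proliferation lists. Among 36 hypoxia and glycolysis genes, the aldolase gene ALDOC was 2.97-fold higher, while the pyruvate dehydrogenase kinase gene PDK1 differed by -0.89, DDIT4 by 0.68 and BHLHE40 by 0.64. The median of this list was 0.11 at percentile 99.2, and it lay inside the random range under 1 of 8 alternative settings. The NRF2 target list had a median of 0.10 at percentile 98.1 but lay inside the random range under 6 of 8 settings, and in it the carbonyl reductase gene CBR1 was 3.84-fold lower. ALDH3A1 (0.56), AKR1C2 (0.41) and HMOX1 (0.41) were higher by less than 2-fold. Of 42 DNA replication genes, 33 were lower and 9 higher, none by 2-fold, with a median of -0.14 at percentile 0.52. The primase subunits PRIM2 (-0.71) and PRIM1 (-0.53) and the origin recognition gene ORC1 (-0.53) were among the lower ones, and GINS4 differed by 0.50. None of 44 mitotic genes differed by 2-fold. The mitotic median of -0.05 lay at percentile 12.1, and HMMR (-0.59), CDC25C (-0.43), KIF20A (-0.36) and NUF2 (-0.33) differed most.

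Growth factors, their receptors and developmental pathways differed at single genes more than as lists. Among 40 growth factor ligands, BMP2 (-2.47) and VEGFC were at least 2-fold lower, and 3 were at least 2-fold higher, WNT5A and GDF15 among them. Among 46 growth factor receptors, MERTK (-1.97) and EPHA4 were at least 2-fold lower and AXL, the receptor of GAS6, was 2.96-fold higher, while TGFBR1 differed by -0.85. With DUSP1 siRNA, BMP2 (3.70) and MERTK (3.91) read below the median level, where the size of a difference is uncertain. Among 20 TGF-beta target genes, ID3 (1.86) and BAMBI (1.15) were at least 2-fold higher, CCN2 at least 2-fold lower, and ID1 differed by 0.95. In the list of Wnt and Notch targets, the Wnt inhibitor gene DKK1 was 3.36-fold lower and JAG1 higher, and HES4 (-0.62) and NRARP (-0.38) differed by less than 2-fold. The medians of these lists were 0.07, -0.03, 0.06 and -0.05, and all lay inside the random range, though growth factor ligands lay above it under 2 of 8 alternative settings, at percentiles 97.8 and 99.6.

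Epithelial and mesenchymal markers had list medians inside the random range. KRT19, a keratin of simple epithelia, was 2.11-fold lower, and OCLN (-0.82), JUP (-0.55) and CDS1 (0.48) differed by less than 2-fold. The epithelial median over 29 genes was 0.11 at percentile 96.9. Of 23 mesenchymal markers, AXL was at least 2-fold higher, and TGFB1I1 (-1.37), TWIST2 (-1.13) and CDH11 (-1.01) were at least 2-fold lower, with a median of 0.05 at percentile 77.4 and a mean of -0.04. Markers of other cell types were also read. The fibroblast list had a median of 0.26 at percentile 99.9, with LUM and COL3A1 far apart in opposite directions and COL1A1 (0.55) and COL1A2 (0.47) higher by less than 2-fold. It lay inside the random range under 2 of 8 settings. No endothelial or leukocyte marker differed by 2-fold, and the list medians were 0.12 and 0.05, both inside the random range. The endothelial markers with the largest differences were CLEC14A (0.45), KDR (-0.37), CDH5 (0.29) and PECAM1 (0.26), and the leukocyte markers were CD14 (0.54), CD3E (0.51), FCER1G (0.39) and CD79A (-0.19). KDR, CDH5, CD3E and FCER1G, like CDS1 and COL1A2, had no probe set at or above the median level. The sizes of their differences are uncertain.

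The remaining lists lay inside the random range, but neuroendocrine markers lay below it under 3 of 8 alternative settings, at percentiles 1.15, 0.04 and 2.38. Of the neuroendocrine markers, NCAM1 was lower, and SYT1 (-0.65), DDC (0.47) and ENO2 (-0.37) differed by less than 2-fold, with a median of -0.06 over 17 genes. No lung lineage marker differed by 2-fold and the median was -0.00. Among them HOPX (-0.88), which lies in a run of neighbouring genes that were mostly slightly lower, MUC5B (0.43), SFTPD (-0.41) and SCGB3A2 (0.38) differed most. DDC, MUC5B, SFTPD and SCGB3A2 had no probe set at or above the median level, so the sizes of their differences are uncertain. The germ cell gene DAZL was lower (6.22 to 3.75) among 22 cancer-testis genes, where MAGEB2 (-0.43), SPANXB1 (0.53) and TEX15 (0.52) differed by less, and the median was 0.04 with a mean of -0.08. SPANXB1 and TEX15 read below the median level on both arrays, and DAZL did so with DUSP1 siRNA, so these sizes are uncertain. Of 14 heat shock genes HSPA2 was 2.95-fold lower, and CRYAB (-0.88), CHORDC1 (0.84) and HSPB1 (-0.73) followed, with a median of -0.06. No apoptosis regulator beyond PMAIP1 differed by more than 0.48, the value of BAK1, with CASP9 at -0.45 and CFLAR at -0.41, and the list had a median of -0.01 and a mean of 0.01. In the small RNA machinery AGO4 (-0.69), TNRC6A (-0.41), TARBP2 (0.34) and MOV10 (-0.28) differed most, with a median of -0.04 over 14 genes. TNRC6A and UQCRC2 lie in a run of neighbouring genes that were mostly slightly lower. Ribosomal protein genes had a median of 0.01 with RPLP2 at 0.37, RPS25 at 0.20, RPL11 at 0.14 and RPL6 at 0.12. Oxidative phosphorylation genes had a median of 0.04, and UQCRC2 (-0.32), COX7B (0.32), CYC1 (0.29) and NDUFB9 (0.27) differed most.

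Repeat readings of a gene by different probe sets gave a measure of reading error within these RNA samples, though not of the variation between cultures. Of 132 genes at least 2-fold apart that had a second probe set at or above the median level, 128 had that probe set differ in the same direction, which is 97.0% (95% Wilson interval 92.5 to 98.8, counting error only), and 71 had it at least 2-fold apart too. Over all 6052 genes with such a pair, 68.5% had both in the same direction. The bacterial spike-in RNAs added at hybridization read 0.41 higher at the median with DUSP1 siRNA (18 of 18 probe sets higher), and the poly-A spike-in RNAs added before labelling read -0.21 (21 of 24 lower). Several of these probe sets read the same spike-in RNA, so they do not count as separate readings. The 3' minus 5' difference of GAPDH was 0.14 on both arrays, and that of beta-actin was 0.12 with empty vector and 0.21 with DUSP1 siRNA.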

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

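With 1 array per group, neither leaving out a replicate nor any test was possible. No paired analysis was possible because each group has 1 array. The DUSP1 difference stayed between -1.75 and -1.78 under 4 alternatives, which could hardly move it. Of these, 1 returned the same probe set, since all 3 probe sets of DUSP1 carry an _s or _x suffix. The others rescaled arrays that were already normalized. The DUSP1 difference came to -1.21 when the 3 probe sets were averaged, since the dimmest hardly differed. Averaging all probe sets of each gene gave 54 genes at least 2-fold higher, 155 lower and 209 in all. Genes at or above the 75th percentile of level gave 46, 125 and 171, as fewer genes were counted. A rule of 1.5 on the log2 scale gave 39, 98 and 137, and a rule of 1.5-fold gave 282, 751 and 1033. Requiring a second probe set at least 2-fold apart, an alternative chosen after seeing the data, gave 19, 52 and 71. Only 132 of the genes at least 2-fold apart had a second probe set at or above the median level, so the rest could not be assessed. The share of lower genes stayed between 69.7% and 75.3% under these settings, the other scalings and filters, and without the runs of neighbouring genes. Shifts by control RNAs, also chosen after seeing the data, moved it: the poly-A spike-ins gave 142, 149 and 291 with 51.2% lower, the hybridization spike-ins 47, 735 and 782 with 94.0%, and the normalization controls 76.7%. Of the 30 genes with the largest differences, 26 stayed at least 2-fold apart the same way when probe sets without an _s or _x suffix were preferred. All 30 did so under the other 4 settings, but sizes depend on the probe set rule. Genes with 1 probe set could not change when all probe sets were averaged or when those without a suffix were preferred. Of 150 named differences besides that of DUSP1, 41 moved by more than the spread of differences between genes when all probe sets were averaged, and 20 moved and 3 reversed when those without a suffix were preferred. LUM (-0.25), COL3A1 (0.13), PIP5K1B (-0.24) and NAV2 were lost there because this rule takes a dim probe set. Under that rule 3 named genes reversed, NAV2 to 0.11, MCAM to 0.21 and IL1A to -0.17, and for MCAM the cause was not tested. Among the settings for lists, centring on the median shifts all genes alike, so it could not change any list's position. Of the 13 lists outside the random range, 9 stayed there under all 8 settings, of which 1, leaving out the runs of neighbouring genes, was chosen after seeing the data. Angiogenic factors left it under 2, hypoxia and glycolysis genes under 1, NRF2 targets under 6 and fibroblast markers under 2. Growth factor ligands came out above it under 2 settings (medians 0.08 and 0.12) and neuroendocrine markers below it under 3 (-0.11, -0.20 and -0.21), and the cause was not tested. Without a filter on level, the share of second probe sets in the same direction was 62.0% over all genes and 90.0% over those at least 2-fold apart, against 68.5% and 97.0%.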

Other observations

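The tests below were all chosen after the results were seen. FST and SOX4 lie outside the rule for named genes and were singled out after their values were seen. FST, the gene of the activin antagonist follistatin, went from 10.10 to 7.79 with DUSP1 siRNA and was lower at all 3 of its probe sets. The transcription factor gene SOX4 differed by -2.52 and was lower at 4 of its 5 probe sets at or above the median level.

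Stretches of neighbouring genes were lower together with DUSP1 siRNA. In genome order, 3 runs had windows of 50 genes whose median lay below the lowest window of 100 shuffles (-0.21), and none lay above the highest. The run from NTN3 to NFATC2IP held 175 genes, of which 139 were lower with a median of -0.25, against -0.03 for the 436 other genes of its chromosome. The run from GAK to CXCL8 held 171 genes, 122 of them lower with a median of -0.22, while the 262 other genes of its chromosome also leaned lower, with a median of -0.07 and 154 lower. The run from OSBPL6 to C2orf69 held 53, 38 of them lower with a median of -0.18, against -0.02 for the 794 others. Because runs were picked for low medians, they were sought again on alternate genes, and the 321 genes that lay inside the runs found so but were not used to find them had a median of -0.18, which 0 of 100 shuffles reached. They lay from NTN3 to ALDOA (median -0.24), from TPSD1 to HIRIP3 (-0.18) and from ZNF721 to ENOPH1 (-0.12). This argues against a chance order of genes for the runs from NTN3 and from GAK, which these overlap, but 0 genes of the run from OSBPL6 were covered, so chance stays open for it. A trend with level left the median of the 399 genes at -0.24 once removed, and a trend with gene length left it at -0.23, so neither accounts for the runs as a whole. A candidate explanation for the run from NTN3 is that the siRNA-expressing cells carry fewer copies of it than the vector cells: of 78 brighter genes not used to find the overlapping runs from NTN3 to ALDOA and from TPSD1 to HIRIP3, which reach past that run, 72 were lower, 92.3%, with a median of -0.33, against 49.7% of brighter genes outside the runs. From ZNF721 to ENOPH1, which overlaps the run from GAK, 29 of 43 such genes were lower, 67.4%, which leaves this open there. This is a hypothesis found and tested on the same arrays, any other cause that acts on a whole region would give the same values, and a trend with GC content and an effect of DUSP1 loss remain open.

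More genes were at least 2-fold lower than higher. The tests of scaling do not decide. Centring, quantile and lowess scaling left the share of lower genes between 69.7% and 74.2%, but the arrays were already normalized, so these could hardly move it. A constant shift moves the share by construction, and the spike-in RNAs disagree on its direction, with 51.2% from the poly-A and 94.0% from the hybridization controls. The runs of neighbouring genes are argued against as the whole cause, since 72.1% of the 294 genes 2-fold apart outside them, among those with a known position, were lower. The effect of the siRNA, an off-target effect and differences between the selected cells and the vector cells may each give such a split, and with 1 array per group they cannot be separated.

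COL3A1, COL12A1 and LOXL2, genes that fibroblasts express, went from 6.19 to 9.05, from 3.70 to 7.04 and from 4.52 to 8.68 at their brightest probe sets, the latter 2 from below the median level. Fibroblasts in the siRNA culture would bring their other abundant transcripts, but the other 11 fibroblast markers had a median of 0.25 (quartiles 0.06 and 0.39), none was at least 2-fold higher, and LUM differed by -5.12. Of all 14 probe sets of these genes, whatever their level, 7 were at least 2-fold higher and the other 7 differed by less. A single faulty probe set per gene is argued against, since each gene had at least 2 that were 2-fold higher (3 of 5 for COL3A1, 2 of 5 for COL12A1 and 2 of 4 for LOXL2). However, the raised probe sets of COL3A1 and LOXL2 all carry an _s or _x suffix. Those of COL3A1 without a suffix differed by 0.04 and 0.13. Whether the raised probe sets are independent readings, and why the others differed less, was not tested. A change in the H460 cells themselves, by DUSP1 loss or by selection of a clone, stays open and was not tested.

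Among 2990 probe sets at or above the median level that are unnamed here, 7 were at least 2-fold higher and 39 at least 2-fold lower with DUSP1 siRNA. The largest differences among them were -3.49 at 204870_s_at and 2.33 at 204614_at.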
